A study of Homo sapiens with 12 samples.

How the data were processed

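Gene expression was measured by RNA-seq in 12 samples of astrocytes derived from H9, an established human embryonic stem cell line. The labels place them in 4 groups of 3: dorsal forebrain (DFB), ventral forebrain (VFB), dorsal spinal cord (DSC) and ventral spinal cord (VSC). Per the labels, astrocyte progenitors received BMP4 and CNTF, a pair of factors that drive astrocyte differentiation, at 10 ng/mL for 7 days. Total RNA was then purified on Qiagen RNeasy columns and made into Illumina libraries. The submitters' processing notes name Bowtie, a read aligner, and RSEM, which estimates the number of reads that belong to each gene. They give no versions and no strand, and the genome build is not given in the sources used here, so no coordinates are printed. Genes are identified by the symbols in the deposited table.

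The deposited values are a normalized signal per gene: RSEM expected counts that the authors divided by 1 size factor per library, with no correction for gene length and no logarithm. This was checked on the values. In every library, 100% of values under 1000 reads were multiples of a hundredth of a read (tolerance 0.02 hundredths). Of the values under 20 reads, 74.6% to 77.4% were whole reads (tolerance 0.001 reads). The size of 1 read in each library gave its depth, from 18.1 to 26.9 M estimated reads, against normalized totals of 22.9 to 24.804 M. The authors also deposited a score per gene, the posterior probability of each of 5 expression patterns, under column names like those of the program EBSeq. The patterns are not defined in the file, and the scores were used only for the closing observations. Further sheets repeat group means, for all genes in 1 sheet and for 53 genes in another.

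Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(value + 1). Genes with a value of at least 1 in at least 3 samples were tested, which kept 16443 of 17530 genes (93.8%). A single model with 1 mean per group and 8 residual degrees of freedom gave 6 contrasts: both spinal cord groups against both forebrain groups, VFB against DFB, VSC against DSC, DSC against DFB, VSC against VFB, and the difference between the spinal cord and forebrain dorsoventral effects, called the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. The plan had held a count-based test for raw counts, and limma was its option for normalized values. A gene was counted as not overlapping when every library of one side of a contrast lay above every library of the other, a condition that has no meaning for the interaction and was not applied there.

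Each of 38 gene lists, named with its result in the report, was tested with camera in limma at a preset correlation of 0.01 between genes when at least 5 members were tested. This held for 36 lists, and camera p values were adjusted over the lists of a contrast. Camera was also run with the correlation estimated from the residuals of each list, and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, was run as another test. Older gene symbols were matched through reference synonyms. The named genes were set by a rule. For each contrast it took the 6 largest increases and 6 largest decreases (4 each for the interaction) among called genes with a mean of at least 5 over the 12 samples and no overlap. From each list it took up to 4 members with the largest changes, and any member needed to describe the list.

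Groups at 0 reads were given a floor of 3 reads over the whole group, and folds against them are printed as lower bounds. List medians given at the bound leave out genes with at most 3 reads in both groups compared. For groups at 1 to 3 reads, the ratio of the means is printed with its 95% exact counting interval. Floors and intervals cover counting error only, since reads copied by PCR are not independent molecules. Read depth differed by less than 1.5 times between libraries.

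The groups, contrasts, tests, gene lists, naming rule and alternatives were fixed before the data were examined, apart from the additions named here. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 in 3 samples, TMM-type scaling, quantile normalization, no trend, array quality weights, a fit on the groups of the contrast alone, a threshold of 0.01, a minimum log2 fold change of 1, replicate number as a block, and leaving out each library in turn. A voom fit on the estimated reads was added after seeing the data, as were 5 short gene lists used in the closing section. The workflow was tested on simulated data of the same form, with 16316 genes tested. It recovered 50 of 67 genes shifted by 0.5 on the log2 scale (74.6%), 61 of 67 shifted by 1 and 66 of 66 shifted by 2, with 11 false calls among 16095 unchanged genes. In the simulated contrast with no change it called 0 genes. The shifted list of 21 genes was the single list called. The simulated genes were drawn independently of each other, so this does not test list calls among correlated genes. Genes shifted singly were taken from those with higher means. All groups had the same spread, with the largest spreads capped, and most genes were unchanged. These rates were therefore not measured for genes near 0 reads, for a group with wider spread or for contrasts where most genes change. No sample was left out.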

Results

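RNA-seq measured gene expression in astrocytes, the glial cells that support neurons, made from the H9 human stem cell line along 4 regional routes. The labels name dorsal forebrain (DFB), ventral forebrain (VFB), dorsal spinal cord (DSC) and ventral spinal cord (VSC), with 3 libraries each. The series title describes regionally specified astrocytes, so the comparisons ask how expression differed between forebrain and spinal cord and between the dorsal and ventral side of each. Depth ran from 18.1 to 26.9 M estimated reads per library, and 15665 to 16308 of 17530 genes had a value above 0. Expression is given in normalized reads as group mean ± SD over 3 libraries, and log2 fold changes as limma estimate ± SE. Counts beside a list test were adjusted over all genes, and those adjusted over the list alone are given as "list alone". Every gene outside the fixed lists that is named for its fold change had no overlap between the libraries compared. Nothing in the labels says that the libraries of a group came from separate cultures, so the p values measure the spread between samples, whatever its source.

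Across genes, which are not independent replicates, libraries of the same group correlated with r from 0.991 to 0.993 on the log2 scale, and libraries of different groups with r from 0.923 to 0.987. For genes with more than 50 reads, the mean chi-square per gene between the reads of 2 libraries was 8.99 to 10.2 within DFB and 1.73 to 4.89 within the other groups, against 1 for counting error alone. DSC and VSC were the closest pair of groups, with a mean r of 0.9865. DFB stood farthest from the others, with mean r from 0.925 to 0.938. The first 2 principal components held 53.5% and 30.0% of the variance. Of the gene list calls given below at a preset correlation, those that held with an estimated correlation were the HOX paralogue groups 1 to 5 in 3 comparisons, the forebrain transcription factors and neural progenitor markers in 2 comparisons each, and the ventral spinal cord and interferon response lists in the interaction.

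The comparison of both spinal cord groups with both forebrain groups addressed position along the rostrocaudal axis. Several HOX genes of groups 2 to 4, which set position along the hindbrain and upper spinal cord, were high in both spinal cord groups. HOXB3 averaged 2716 ± 109 in DSC and 2871 ± 168 in VSC against 6.34 ± 2.00 in DFB and 5.79 ± 1.42 in VFB, a log2 fold change of 8.66 ± 0.13 (limma adjusted p = 6.2e-19). HOXA3 (8.47 ± 0.16), HOXB4 (8.08 ± 0.21), HOXA2 (8.07 ± 0.31) and HOXB2 (7.79 ± 0.28) had the next largest increases. HOXA4 rose from 0.458 ± 0.792 in DFB and 0.366 ± 0.635 in VFB to 251 ± 5.96 in DSC and 285 ± 10.5 in VSC. All 12 tested genes of HOX paralogue groups 1 to 5 were higher in spinal cord (list alone 12, camera adjusted p = 6.14e-08, 0.00904 with an estimated correlation). All 9 tested genes of groups 6 to 9, which pattern the thoracic cord, were higher as well (list alone 9, camera adjusted p = 0.000352, adjusted p = 0.0676 with an estimated correlation). For some of them this came from DSC. HOXB6, HOXB8 and HOXB9 had 114, 207 and 537 reads over the DSC libraries, against 8, 6 and 1 over the VSC libraries. HOXA7 had 297 in DSC and 418 in VSC. Groups 10 to 13, which mark the lumbosacral cord, had 3 tested genes of 12, too few for a list test. Of these 2 were lower in spinal cord, among them HOXD13, and HOXA10 was not called. Reads were few, with HOXD13 at 10 over the VFB libraries, 4 over DSC and 1 over VSC. HOXA10 had 2 over VFB, 2 over DSC and 4 over VSC.

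Forebrain regulators showed the opposite. OTX2, a regulator of the anterior neural plate, averaged 1414 ± 10.1 in DFB and 745 ± 17.6 in VFB, against 12.3 ± 2.56 in DSC and 21.5 ± 2.67 in VSC (log2 fold change -5.91 ± 0.10, limma adjusted p = 2.9e-18). Of 12 tested forebrain transcription factors, 11 were lower in spinal cord, including LHX2 (-4.02), and DMRTA2 was not called (list alone 11, camera adjusted p = 3.78e-05, 0.0153 with an estimated correlation). PIEZO2, which encodes a mechanosensitive ion channel, averaged 364 ± 49.7 in DFB and 593 ± 12.1 in VFB, against 0.962 ± 0.984 in DSC and 1.30 ± 0.577 in VSC. KCNH7, a potassium channel gene, and NR2E1, a nuclear receptor gene of neural stem cells, had log2 fold changes of -6.82 ± 0.31 and -6.40 ± 0.32. FAM5C was also among the largest decreases (-6.68 ± 0.26). The neural progenitor and radial glia markers were lower for 15 of 16 genes, including SOX1 (-4.35), HES5 (-3.97) and LIX1 (-3.02) (list alone 15, camera adjusted p = 8.91e-06, 0.013 with an estimated correlation). Of 16 ventral forebrain genes, 11 were lower and 2 higher, with SP8 at -3.13 (list alone 11 lower and 2 higher, camera adjusted p = 0.00718, adjusted p = 0.267 with an estimated correlation). In VSC against VFB the ventral forebrain list was not called (median -0.93, camera adjusted p = 0.752). SP8 averaged 2569 in DFB, 12.6 in VFB, 211 in DSC and 1.62 in VSC, so its decrease reflects DFB. DLX1 averaged 7870 in DFB, 347 in VFB, 1803 in DSC and 2133 in VSC. DLX2, DLX5 and DLX6 also averaged less in VFB than in either spinal cord group, while NKX2-1, LHX6 and LHX8 averaged more.

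**Figure D1:**
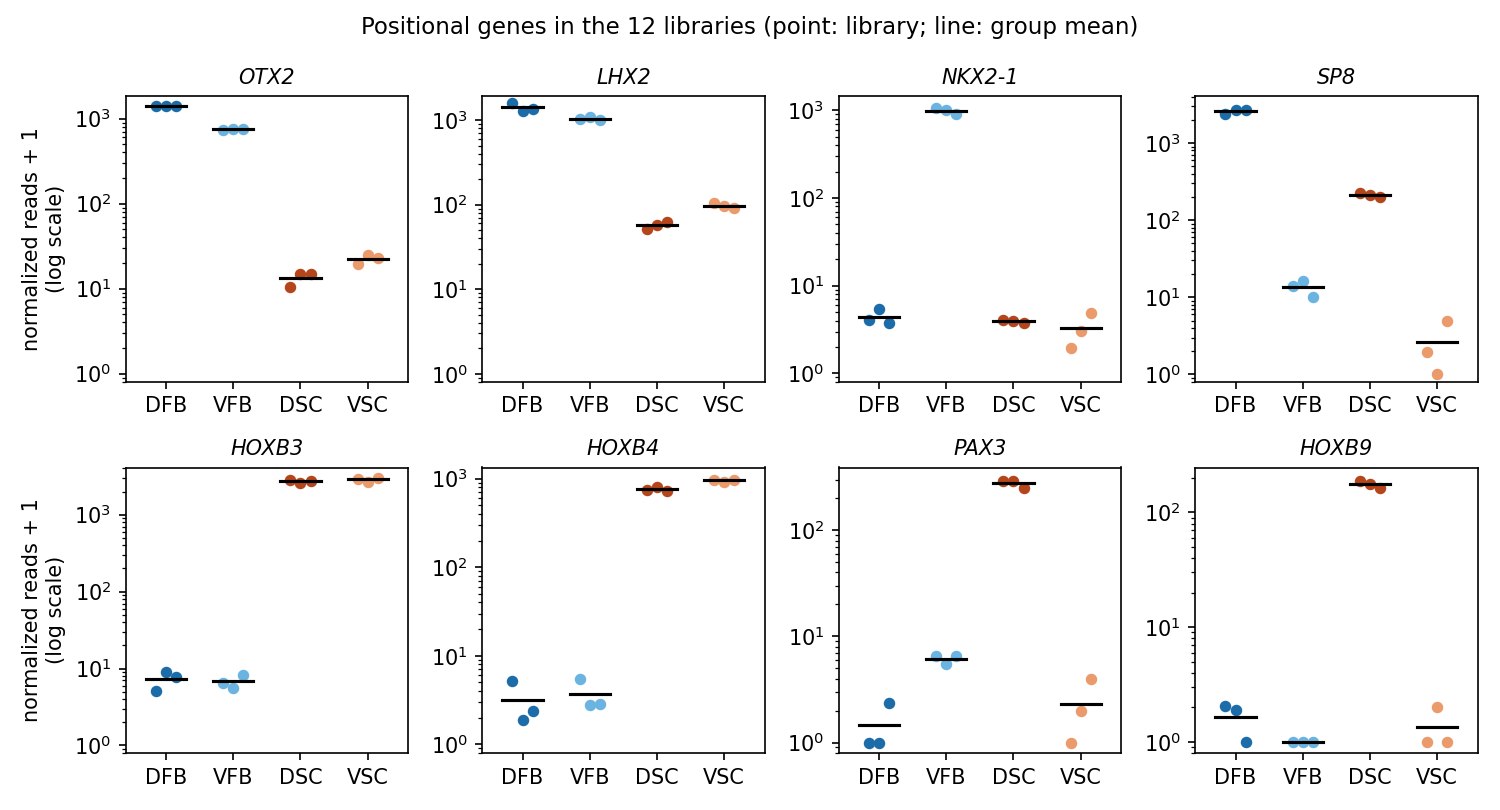
Normalized reads plus 1 on a log axis for 8 positional genes, with 1 point per library, a line at each group mean, and the groups DFB, VFB, DSC and VSC on the horizontal axis. OTX2 averaged 1414 in DFB and 21.5 in VSC, NKX2-1 averaged 987 in VFB, HOXB3 averaged 2716 and 2871 in the spinal cord groups, and PAX3 and HOXB9 averaged 277 and 175 in DSC.

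Astrocytes of all 4 groups expressed GFAP, the intermediate filament gene of astrocytes, but genes for astrocyte transport were lower in spinal cord. AQP4, the water channel gene, averaged 14733 ± 943 in DFB and 21459 ± 790 in VFB, against 1679 ± 142 in DSC and 806 ± 231 in VSC (log2 fold change -3.95 ± 0.09, limma adjusted p = 1.6e-16). SLC6A11, a GABA transporter gene, was lower too (-3.60), and GRIA3, an AMPA receptor subunit gene, was higher. Of 23 tested genes for glutamate, potassium and calcium handling, 18 were lower and 4 higher (list alone 18 and 4, camera adjusted p = 0.000185, adjusted p = 0.326 with an estimated correlation). The 24 astrocyte markers divided into 12 lower, 10 higher and 2 not called (list alone 12 lower and 10 higher, camera adjusted p = 0.305).

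**Figure D2:**
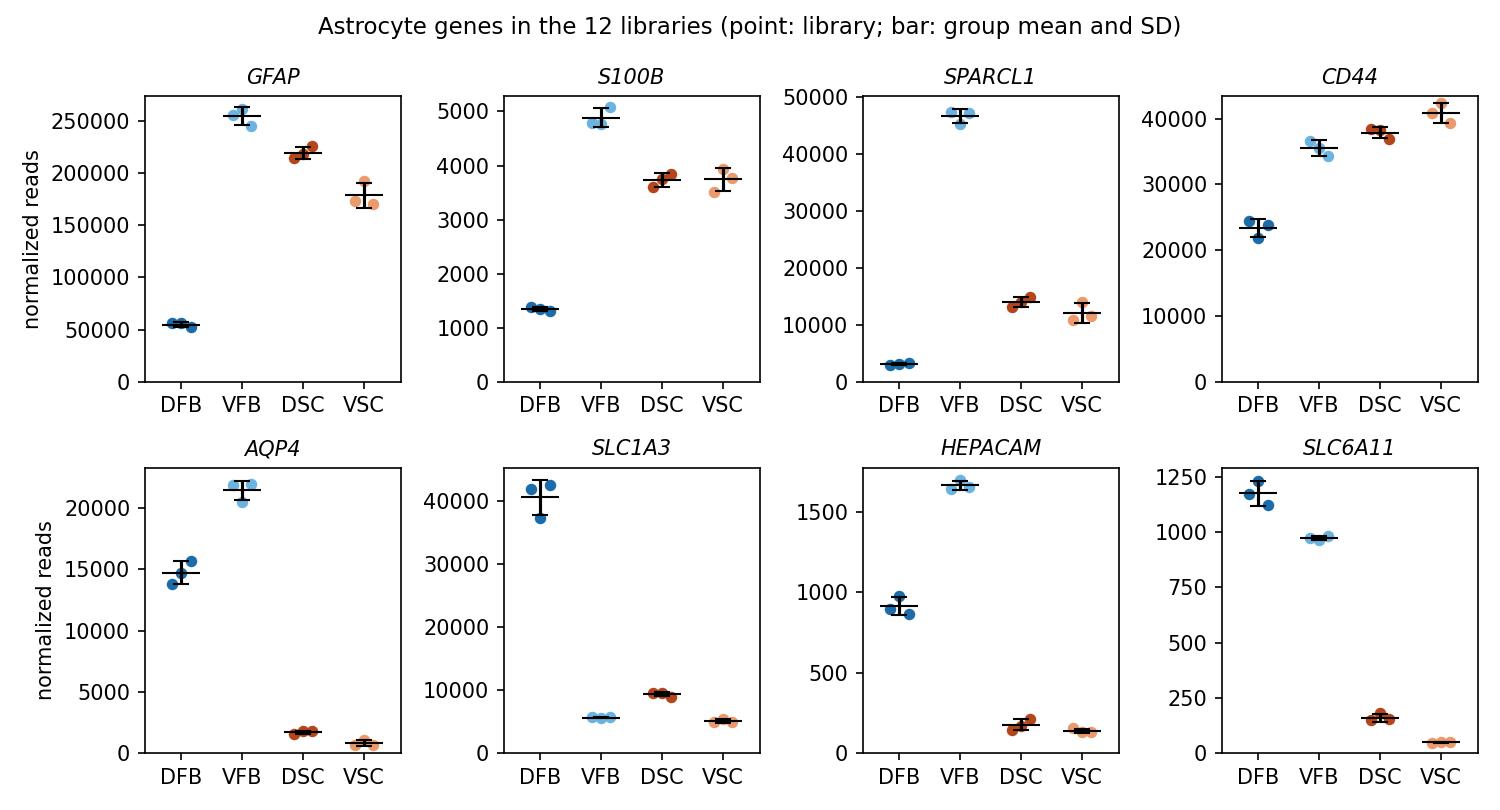
Normalized reads on linear axes from 0 for 8 astrocyte genes, with 1 point per library, and a horizontal bar and whiskers for the mean and SD of 3 libraries in each of the groups DFB, VFB, DSC and VSC. GFAP averaged 54878 in DFB and 254113 in VFB, and AQP4 averaged 14733 in DFB and 806 in VSC.

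Matrix genes rose in spinal cord for 21 of 30 list members and fell for 9, with TGFBI at 4.90, COL1A1 at 3.49 and LUM at -4.26 (list alone 21 and 9, camera adjusted p = 0.000904, adjusted p = 0.311 with an estimated correlation). All 8 tested A1-type reactive genes, a set described in astrocytes after inflammatory stimulation, were higher in spinal cord, including GBP2 (2.53) and FBLN5 (2.37) (list alone 8, camera adjusted p = 0.00179, adjusted p = 0.311 with an estimated correlation). WNT response genes were higher for 9 of 13, including LEF1 (2.80) and NKD1 (2.56), and lower for 4 (list alone 9 and 4, camera adjusted p = 0.015, adjusted p = 0.311 with an estimated correlation). Ribosomal protein genes were higher for 29 of 30, with a median log2 fold change of 0.38 (list alone 30, camera adjusted p = 4.32e-08, adjusted p = 0.337 with an estimated correlation). Glycolysis and hypoxia genes were higher for 17 of 24 and lower for 5 (list alone 17 and 5, camera adjusted p = 0.00718, adjusted p = 0.53 with an estimated correlation). Cholesterol synthesis genes were lower for 17 of 21, with HMGCS1 at -1.51, and higher for 1 (list alone 17 and 1, camera adjusted p = 0.000178, adjusted p = 0.296 with an estimated correlation). Immediate early and stress genes were lower for 13 of 19 and higher for 4 (list alone 13 and 4, camera adjusted p = 0.0149, adjusted p = 0.556 with an estimated correlation). Of these lists 6 were not called on 1 of the sides. In VSC against VFB, matrix genes were higher for 15 of 30 and lower for 14 (list alone 15 and 14, camera adjusted p = 0.937). A1-type genes were higher for 5 of 8 and lower for 1 (list alone 5 and 1, camera adjusted p = 0.219), and WNT response genes higher for 7 of 13 and lower for 3 (list alone 7 and 4, camera adjusted p = 0.302). Cholesterol synthesis genes were lower for 11 of 21 and higher for 4 (list alone 12 and 4, camera adjusted p = 0.127), and immediate early and stress genes higher for 6 of 19 and lower for 3 (list alone 6 and 3, camera adjusted p = 0.757). In DSC against DFB, glycolysis and hypoxia genes were higher for 11 of 24 and lower for 10 (list alone 11 and 10, camera adjusted p = 0.996). The interaction, given below, was called for each of these 6 lists.

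Neural crest markers were higher in spinal cord for 9 of 12 genes and lower for 2, with TFAP2A at 6.12 and TFAP2B at 4.69 (list alone 9 and 2, camera adjusted p = 0.00718, adjusted p = 0.0909 with an estimated correlation). Mesenchymal and fibroblast markers were higher for 11 of 17 and lower for 4, with ACTA2, a smooth muscle actin gene, at 4.13 and TAGLN at 3.67 (list alone 11 and 4, camera adjusted p = 0.0224, adjusted p = 0.267 with an estimated correlation). In VSC against VFB neither list was called, with 6 of 12 neural crest genes higher and 3 lower (list alone 6 and 3, camera adjusted p = 0.302) and 8 of 17 mesenchymal genes higher and 6 lower (list alone 8 and 6, camera adjusted p = 0.694). The interaction was called for the mesenchymal list and not for the neural crest list. Microglia markers were near the detection limit, with 4 of 11 genes tested and PTPRC, a leukocyte gene, at 6.58 ± 1.17 in VFB and 0 reads in the other groups.

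Of 16443 tested genes, 5695 were higher and 5944 lower in spinal cord, and 1506 and 1459 of these differed at least 2-fold. Libraries of both sides did not overlap for 4983 genes. The 0.216% expected by chance holds only if all libraries are exchangeable. They are not, since libraries of the same group resembled each other more than those of other groups. The number of genes without overlap therefore does not measure the size of the axis effect. Camera called 15 of 36 lists, a count reached by 6 of 100 groupings of the samples into 6 and 6, the real one included, with a maximum of 17, so chance is not excluded for the number of lists.

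The comparison of VFB with DFB addressed dorsoventral identity in the forebrain. NKX2-1, the regulator that specifies the ventral telencephalon, averaged 987 ± 76.4 in VFB and 3.43 ± 0.902 in DFB (log2 fold change 7.82 ± 0.30, limma adjusted p = 3.5e-13). LHX6, which acts downstream of NKX2-1, had a ratio of 297 (95% counting interval 43.9 to 9772), FOXA1 a ratio of 196 (55.8 to 798) and LHX8 a ratio of 37.9 (11.6 to 362). SHH, the ventralizing signal, was at least 26.4-fold higher in VFB. The ventral spinal cord list, which shares such ventral regulators, had 10 of 13 tested genes higher in VFB and none lower, including NKX2-2 (6.09) and NKX6-1 (5.11) (list alone 10, camera adjusted p = 0.00233, adjusted p = 0.119 with an estimated correlation).

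The ventral forebrain list itself did not move one way, with 7 of 16 genes higher in VFB and 9 lower (list alone 7 and 9, camera adjusted p = 0.262). DLX1, a regulator of GABAergic neurons, averaged 7870 ± 459 in DFB and 347 ± 27.1 in VFB (-4.50). DLX2 (-4.76), DLX5 (-5.47), DLX6 (-4.75) and SP8 (-7.59 ± 0.37) were likewise lower in VFB. GSX2, a regulator of the lateral ganglionic eminence, had a log2 fold change of -6.98 ± 0.35. SCGN, a calcium-binding protein gene, averaged 5340 ± 203 in DFB and 23.1 ± 7.23 in VFB (-7.83 ± 0.20). The dorsal forebrain list had 4 genes higher in VFB, 3 lower and 6 not called of 13 (list alone 4 and 3, camera adjusted p = 0.919), with PAX6 at -1.40, GLI3 at -1.05, WNT7B at 3.11 and EMX2 at 3.05. On the hedgehog response list, GLI1 had a ratio of 39.5 (95% counting interval 12.01 to 373) and GAS1 a log2 fold change of -2.76 (6 higher and 4 lower of 13, list alone 6 and 5, camera adjusted p = 0.839). The list was not divided into genes that hedgehog signalling raises and genes that it lowers, so its test does not measure the response.

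Astrocyte genes differed strongly between the forebrain groups. GFAP averaged 254113 ± 8569 in VFB and 54878 ± 2152 in DFB (log2 fold change 2.21), and SPARCL1, a secreted synapse-promoting glycoprotein gene, averaged 46561 ± 1205 and 3097 ± 201 (3.91). SLC1A3, a glutamate transporter gene, was lower in VFB, at 5603 ± 110 against 40528 ± 2798 (-2.85), and so was FABP7, a fatty acid binding protein gene of radial glia (-1.75). Of 24 astrocyte markers, 13 were higher and 10 lower (list alone 13 and 10, camera adjusted p = 0.714). Synapse-modulating secreted and adhesion genes were higher in VFB for 15 of 23 and lower for 5, including THBS1 (3.16) and WNT5A (3.26) (list alone 15 and 5, camera adjusted p = 0.013, adjusted p = 0.162 with an estimated correlation). HSPB8, a small heat shock protein gene, had the largest increase, from 8.33 ± 1.24 in DFB to 4982 ± 178 in VFB (9.07 ± 0.09, limma adjusted p = 3.1e-20). IRX1 (8.78 ± 0.35) and COL21A1 (8.02 ± 0.23) were also among the largest increases, and FNDC1 had a ratio of 374 (95% counting interval 125 to 1771).

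Matrix genes were higher in VFB for 25 of 30 and lower for 5, with COL3A1 at 4056 ± 383 against 9.50 ± 1.38 in DFB (8.60 ± 0.10) and DCN at least 183-fold higher (list alone 25 and 5, camera adjusted p = 3.96e-06, adjusted p = 0.162 with an estimated correlation). Interferon response genes were higher for 20 of 23 and lower for 2, including IFI27 (3.00) and IFIT2 (2.84) (list alone 20 and 2, camera adjusted p = 8.88e-05, adjusted p = 0.106 with an estimated correlation). WNT response genes were higher for 12 of 13, including LEF1 (2.76) (list alone 12, camera adjusted p = 0.00298, adjusted p = 0.197 with an estimated correlation). All 22 cell cycle genes were lower in VFB, with a median of -1.52, and MKI67, a marker of dividing cells, fell from 12855 ± 1374 to 4365 ± 156 (list alone 22, camera adjusted p = 1.65e-11, adjusted p = 0.162 with an estimated correlation). Glycolysis and hypoxia genes were lower for 20 of 24 and higher for 3, with HK2 at -3.65 (list alone 20 and 3, camera adjusted p = 1.78e-05, adjusted p = 0.261 with an estimated correlation). Cholesterol synthesis genes were lower for 17 of 21 and higher for 1, including INSIG1 (-1.93) (list alone 17 and 1, camera adjusted p = 8.75e-05, adjusted p = 0.197 with an estimated correlation). Ribosomal protein genes were lower for 29 of 30, with a median of -0.34 (list alone 29, camera adjusted p = 1.11e-06, adjusted p = 0.396 with an estimated correlation).

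Immediate early and stress genes were lower in VFB for 14 of 19 and higher for 4 (list alone 14 and 4, camera adjusted p = 0.00021, adjusted p = 0.396 with an estimated correlation). EGR1, a transcription factor gene induced within minutes of stimulation, averaged 26919 ± 3244 in DFB and 374 ± 10.8 in VFB (-6.16). FOSB (-7.10 ± 0.51) and EGR3 (-6.26 ± 0.17) were among the largest decreases, as was GPD1, a glycerol phosphate dehydrogenase gene (-6.93 ± 0.09). HSPA1A and HSPA1B had large spreads in DFB, at 15616 ± 4977 and 28259 ± 8156, and as near-identical genes they share reads, so how their reads divide is uncertain. Neuron markers were lower in VFB for 12 of 20 and higher for 3, with GAD2 at -4.83 and NEFL at 3.88 (list alone 12 and 3, camera adjusted p = 0.00665, adjusted p = 0.24 with an estimated correlation).

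Markers of further cell types moved with the forebrain groups. Oligodendrocyte lineage markers were higher in VFB for 11 of 13 tested genes, including OLIG1 (3.44) and GPR17 (6.29), with PDGFRA lower (-2.53) (list alone 11 and 1, camera adjusted p = 0.00471, adjusted p = 0.162 with an estimated correlation). Choroid plexus and ependymal markers were higher for 11 of 14, with FOXJ1, the regulator of motile cilia, at 4.42 and DNAH9 at 4.26 (list alone 11 higher and 1 lower, camera adjusted p = 0.00189, adjusted p = 0.134 with an estimated correlation). Mesenchymal and fibroblast markers were higher for 13 of 17 and lower for 4, with TWIST1 at least 26.0-fold higher (list alone 13 and 4, camera adjusted p = 0.013, adjusted p = 0.173 with an estimated correlation).

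In all, 6014 genes were higher and 5387 lower in VFB, with 2434 and 1293 of them at least 2-fold. Quantile normalization turned the majority, with 5426 higher and 6195 lower. The 3 libraries of each group did not overlap for 11605 genes, against 10% expected by chance. Camera called 14 of 36 lists.

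The comparison of VSC with DSC addressed dorsoventral identity in the spinal cord. PAX7 and PAX3, regulators of dorsal neural progenitors, were lower in VSC. PAX7 averaged 163 ± 2.74 in DSC and was at least 168-fold lower in VSC, where it had 0 reads. PAX3 averaged 277 ± 22.6 and 1.32 ± 1.501 (log2 fold change -7.12 ± 0.44, limma adjusted p = 5.7e-09). HOXB9 averaged 175 ± 13.1 in DSC, a ratio of 525 to VSC (95% counting interval 96.3 to 21330). HOXB8 (-4.58), HOXB6 (-3.49) and HOXB7 (-2.71) were lower as well, while HOXA7 was not called (96.6 ± 7.71 in DSC and 136 ± 10.9 in VSC). Of 9 tested genes of HOX paralogue groups 6 to 9, 4 were lower and 5 not called (list alone 5 lower and 1 higher, camera adjusted p = 0.0433, adjusted p = 0.223 with an estimated correlation). None of the 12 tested genes of groups 1 to 5 was lower, and 1 was higher (list alone 0, camera adjusted p = 0.111). Of 13 dorsal spinal cord genes, 4 were lower and 1 higher, with ZIC1 at -1.11 (list alone 4 and 1, camera adjusted p = 0.019, adjusted p = 0.157 with an estimated correlation).

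Ventral regulators did not rise in VSC as a group. NKX6-1, which marks ventral progenitors, averaged 423 ± 42.7 in DSC and 482 ± 49.2 in VSC and was not called, nor was NKX2-2 (230 ± 37.1 and 372 ± 24.799). OLIG2, the regulator of motor neuron and oligodendrocyte progenitors, was higher in VSC (0.76), while DBX2 was lower (-2.78) and DBX1 at least 8.74-fold lower. Of 13 tested ventral spinal cord genes, 1 was higher and 4 lower (list alone 2 and 4, camera adjusted p = 0.63). Hedgehog response genes had 0 higher, 2 lower and 11 not called (list alone 1 and 2, camera adjusted p = 0.964). SP8 averaged 211 ± 11.1 in DSC and 1.62 ± 2.06 in VSC (-6.64 ± 0.37). NDNF, a secreted neurotrophic factor gene, had a ratio of DSC to VSC of 170.4 (95% counting interval 31.1 to 6976), and SLITRK6 a log2 fold change of -5.16 ± 0.40.

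Increases in VSC were smaller. GABRP, a GABA receptor subunit gene, averaged 27.95 ± 3.81 in VSC, 28.5 times its level in DSC (95% counting interval 9.45 to 141). SERPINI1, the neuroserpin gene, rose from 221 ± 7.54 to 921 ± 56.2 (2.05 ± 0.19, limma adjusted p = 6.2e-07). SLITRK3 rose from 14.2 ± 3.62 to 64.4 ± 5.27 (2.13 ± 0.18) and RYR2, a calcium release channel gene, from 22.7 ± 8.49 to 89.9 ± 13.3 (1.99 ± 0.28). TSTD1 (2.64 ± 0.34) and LTF completed the largest increases. TFAP2A, a neural crest regulator, averaged 106 ± 10.7 in DSC and 415 ± 22.0 in VSC (1.97).

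Matrix genes were lower in VSC for 14 of 30 and higher for 4 (list alone 16 and 4, camera adjusted p = 3.51e-06, adjusted p = 0.15 with an estimated correlation). FN1, the fibronectin gene, averaged 10768 ± 583 in DSC and 1630 ± 29.0 in VSC (-2.72), and COL8A1 averaged 2219 ± 81.1 and 194 ± 32.4 (-3.52). DKK1, a secreted WNT inhibitor gene, averaged 103 ± 4.71 and 6.14 ± 1.26 (-3.87). Of 24 astrocyte markers, 8 were lower and 2 higher, including AQP4 (-1.09) and SLC1A3 (-0.88) (list alone 11 and 3, camera adjusted p = 0.0234, adjusted p = 0.278 with an estimated correlation). Pan-reactive astrocyte genes were lower for 6 of 11, including SERPINA3 (-1.47) and CP (-0.70) (list alone 6, camera adjusted p = 0.00969, adjusted p = 0.193 with an estimated correlation). Synapse-modulating genes were lower for 8 of 23 and higher for 2, with CHRDL1 at -1.18 (list alone 10 and 2, camera adjusted p = 0.0234, adjusted p = 0.15 with an estimated correlation). Axon guidance genes were lower for 14 of 30 and higher for 7, with SLIT3 at -2.41 and SLIT1 at 1.15 (list alone 15 and 8, camera adjusted p = 0.0261, adjusted p = 0.231 with an estimated correlation).

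Cell cycle genes were higher in VSC for 18 of 22, with a median of 0.25 and AURKB, a mitotic kinase gene, at 0.36 (list alone 20, camera adjusted p = 7.12e-11, adjusted p = 0.15 with an estimated correlation). Neuron markers were higher for 10 of 20 and lower for 2, with STMN2 at 0.53 and GAD2 at -1.72 (list alone 10 and 2, camera adjusted p = 0.019, adjusted p = 0.278 with an estimated correlation). Ribosomal protein genes were higher for 6 of 30, with a median of 0.07 (list alone 6, camera adjusted p = 0.000242, adjusted p = 0.56 with an estimated correlation). Interferon response genes were lower for 8 of 23 and higher for 1, with IFI27 at -1.05 (list alone 8 and 1, camera adjusted p = 0.0012, adjusted p = 0.123 with an estimated correlation). Immediate early and stress genes were lower for 8 of 19, with EGR3 at -1.23 (list alone 9, camera adjusted p = 0.000698, adjusted p = 0.407 with an estimated correlation). Choroid plexus and ependymal markers were lower for 8 of 14 and higher for 1, with KCNJ13 at -1.75 and AQP1 at 0.46 (list alone 11 and 1, camera adjusted p = 5.55e-06, adjusted p = 0.056 with an estimated correlation). Midbrain and hindbrain transcription factors were lower for 5 of 14, with WNT1 at -1.08 (list alone 8, camera adjusted p = 0.00581, adjusted p = 0.15 with an estimated correlation). Skeletal and smooth muscle markers were lower for 3 of 10, with ACTG2 at -2.40 and MYH11 at -1.34 (list alone 4, camera adjusted p = 0.019, adjusted p = 0.15 with an estimated correlation).

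In all, 1118 genes were higher and 1651 lower in VSC, with 76 and 461 of them at least 2-fold, and camera called 15 of 36 lists. The 1118 became 724 without DSC replicate 1 and 1745 with array quality weights. The 3 libraries of each group did not overlap for 6129 genes, against 10% expected by chance. The call of HOX paralogue groups 6 to 9 held in 11 of 22 settings, with adjusted p from 0.00258 to 0.189. It was lost without DFB replicate 1 (0.0556), DFB replicate 2 (0.0583), VFB replicate 1 (0.108), VFB replicate 2 (0.0664), VFB replicate 3 (0.0561), DSC replicate 2 (0.0553) or DSC replicate 3 (0.104). It was also lost with a pseudocount of 0.1 (0.189), with no filter (0.0735), under quantile normalization (0.0906) and with replicate block (0.0813). The astrocyte markers call was lost without DSC replicate 3 (0.0538).

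The same rostrocaudal comparison was made within the dorsal side, DSC against DFB. OTX2 was lower in DSC (log2 fold change -6.75 ± 0.14, limma adjusted p = 5.5e-17), and OTX1 averaged 471 ± 13.1 in DFB, a ratio of 700.0 to DSC (95% counting interval 199.9 to 5980). HOXB3 (8.57 ± 0.18) and HOXA3 (8.37 ± 0.23) were higher, HOXA4 had a ratio of 549 (127 to 28040) and HOXB5 was at least 92.7-fold higher. COL14A1, a fibril-associated collagen gene, averaged 12299 ± 253 in DSC and 39.3 ± 7.78 in DFB (8.27 ± 0.09), and PRKCB (8.27 ± 0.21) and CDH13 (8.24 ± 0.19), which encode a kinase and a cadherin, were higher too. STAC had a ratio of 584 (156 to 4677). CALB2, the calretinin gene of interneurons, averaged 3303 ± 437 in DFB and 13.3 ± 2.40 in DSC (-7.86 ± 0.24), and NR2E1 (-8.27 ± 0.45) and KCNH7 (-7.44 ± 0.44) were lower. PIEZO2 had a ratio of DFB to DSC of 378 (126 to 1793).

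All 12 tested genes of HOX groups 1 to 5 were higher in DSC (list alone 12, camera adjusted p = 1.42e-06, 0.0187 with an estimated correlation). So were 8 of 9 of groups 6 to 9 (8, camera adjusted p = 0.00163, adjusted p = 0.078 with an estimated correlation). Forebrain transcription factors were lower for 8 of 12 and higher for 1 (list alone 8 and 1, camera adjusted p = 0.00273, adjusted p = 0.078 with an estimated correlation). Midbrain and hindbrain transcription factors were higher for 10 of 14 and lower for 1, with WNT1 at 5.16 and EGR2 at -3.52 (list alone 10 and 1, camera adjusted p = 0.0244, adjusted p = 0.157 with an estimated correlation). Ventral forebrain genes were lower for 11 of 16 and higher for 2, with GSX2 at -5.43 (list alone 11 and 2, camera adjusted p = 0.00248, adjusted p = 0.122 with an estimated correlation). Dorsal spinal cord genes were higher for 7 of 13 and lower for 3, with PAX3 at a ratio of 605 (139 to 30760) and MSX1 at 5.76 (list alone 7 and 3, camera adjusted p = 0.274). Progenitor markers were lower for 13 of 16 and higher for 1, with SOX1 at -5.56 (list alone 13 and 2, camera adjusted p = 0.000803, adjusted p = 0.0582 with an estimated correlation).

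Functional lists are given next, and since VFB and DSC were both compared with the same 3 DFB libraries, the 2 comparisons are not independent. Matrix genes were higher in DSC than in DFB for 24 of 30 and lower for 5, with TGFBI at 6.64 (list alone 25 and 5, camera adjusted p = 1.42e-06, adjusted p = 0.122 with an estimated correlation). Interferon response genes were higher for 18 of 23 and lower for 3 (list alone 18 and 3, camera adjusted p = 0.0025, adjusted p = 0.078 with an estimated correlation). All 22 cell cycle genes were lower, with a median of -0.97 (list alone 22, camera adjusted p = 1.98e-07, adjusted p = 0.157 with an estimated correlation). Immediate early and stress genes were lower for 14 of 19 and higher for 4, with FOS at -4.97 (list alone 14 and 4, camera adjusted p = 0.00327, adjusted p = 0.394 with an estimated correlation). Cholesterol synthesis genes were lower for 17 of 21 and higher for 2 (list alone 18 and 2, camera adjusted p = 7.45e-05, adjusted p = 0.157 with an estimated correlation). WNT response genes were higher for 9 of 13, with LEF1 at 4.04 (list alone 9, camera adjusted p = 0.00163, adjusted p = 0.14 with an estimated correlation). Ribosomal protein genes were higher in DSC than in DFB for 22 of 30 and lower for 2, with a median of 0.16 (list alone 22 and 2, camera adjusted p = 0.0146, adjusted p = 0.618 with an estimated correlation).

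Astrocyte and support genes gave the following counts. Genes for glutamate, potassium and calcium handling were lower in DSC than in DFB for 16 of 23 and higher for 6, with GRIA2 at -3.50 (list alone 16 and 6, camera adjusted p = 0.00389, adjusted p = 0.35 with an estimated correlation). All 8 A1-type genes were higher, with GBP2 at 5.06 (list alone 8, camera adjusted p = 0.00163, adjusted p = 0.171 with an estimated correlation). Blood-brain barrier and angiogenic factors were higher for 12 of 19 and lower for 1, with LAMA2 at 4.44 and VEGFA at -2.22 (list alone 12 and 1, camera adjusted p = 0.0103, adjusted p = 0.157 with an estimated correlation). Neuron markers were lower for 12 of 20 and higher for 4, with DCX at -3.12 and NEFL at 4.19 (list alone 12 and 4, camera adjusted p = 0.0083, adjusted p = 0.184 with an estimated correlation). Oligodendrocyte markers were higher for 11 of 13 and lower for 2, with BCAS1 at 4.85 (list alone 11 and 2, camera adjusted p = 0.00981, adjusted p = 0.14 with an estimated correlation). Neural crest markers were higher for 8 of 12 and lower for 2 (list alone 8 and 2, camera adjusted p = 0.0237, adjusted p = 0.122 with an estimated correlation). Mesenchymal and fibroblast markers were higher for 13 of 17 and lower for 2, with COL1A1 at 6.03 (list alone 13 and 2, camera adjusted p = 0.00327, adjusted p = 0.114 with an estimated correlation). Choroid plexus and ependymal markers were higher for 10 of 14, with AQP1 at 3.42 (list alone 10, camera adjusted p = 0.00201, adjusted p = 0.078 with an estimated correlation). In all, 6013 genes were higher and 5714 lower in DSC (5571 and 6362 after quantile normalization), with 11892 genes not overlapping against 10% by chance, and camera called 21 of 36 lists. At 2-fold or more, 2439 were higher and 1667 lower.

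Within the ventral side, VSC was compared with VFB. HOXB3 (8.74 ± 0.18, limma adjusted p = 1.5e-16), HOXA3 (8.58 ± 0.23), HOXA2 (8.15 ± 0.44), HOXB4 (8.09 ± 0.30) and HOXB2 (7.71 ± 0.39) were higher in VSC, and HOXA4 had a ratio of 778 (95% counting interval 158 to 34970). NKX2-1 was lower (-8.33 ± 0.30), and SFTA3, its neighboring gene, averaged 428 ± 21.3 in VFB, a ratio of 663 to VSC (182 to 5447). FAM5C (-8.65 ± 0.36), PIEZO2 (-8.04 ± 0.30) and GDA, a guanine deaminase gene (-7.49 ± 0.17), were lower, and MMRN1, the multimerin gene, was at least 191-fold lower. All 12 tested genes of HOX groups 1 to 5 were higher (list alone 12, camera adjusted p = 4.54e-09, 0.00608 with an estimated correlation). So were 7 of 9 of groups 6 to 9 (7, camera adjusted p = 0.00376, adjusted p = 0.153 with an estimated correlation). Forebrain transcription factors were lower for 11 of 12 (list alone 12, camera adjusted p = 7.49e-07, 0.00775 with an estimated correlation). Progenitor markers were lower for 14 of 16, with 1 higher and LIX1 at -5.18 (list alone 15 and 1, camera adjusted p = 2.47e-06, 0.00775 with an estimated correlation).

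Transport and marker genes of astrocytes were lower in VSC than in VFB. Of 23 genes for glutamate, potassium and calcium handling, 20 were lower and 1 higher, including SLC6A11 (-4.33) and KCNJ16 (-4.73) (list alone 21 and 1, camera adjusted p = 2.5e-07, adjusted p = 0.162 with an estimated correlation). Astrocyte markers were lower for 17 of 24 and higher for 3, including AQP4 (-4.77) and HEPACAM (-3.58) (list alone 18 and 3, camera adjusted p = 0.000251, adjusted p = 0.153 with an estimated correlation). Cell cycle genes were higher for all 22, with a median of 0.77 (list alone 22, camera adjusted p = 3.56e-10, adjusted p = 0.153 with an estimated correlation). Ribosomal protein genes were higher for all 30, with a median of 0.56 (list alone 30, camera adjusted p = 6.67e-12, adjusted p = 0.205 with an estimated correlation). Glycolysis and hypoxia genes were higher for 22 of 24, with CA9 at 2.03 and SLC2A1 at 1.81 (list alone 22, camera adjusted p = 2.27e-08, adjusted p = 0.161 with an estimated correlation). Interferon response genes were lower for 16 of 23 and higher for 4, with IFI44L at -2.92 (list alone 16 and 4, camera adjusted p = 0.022, adjusted p = 0.153 with an estimated correlation). Choroid plexus and ependymal markers were lower for 10 of 14 and higher for 2, with TEKT1 at -6.00 (list alone 10 and 3, camera adjusted p = 0.0218, adjusted p = 0.153 with an estimated correlation). In all, 5090 genes were higher and 4983 lower in VSC (5008 and 5060 with TMM-type scaling), with 11323 genes not overlapping against 10% by chance, and camera called 11 of 36 lists. At 2-fold or more, 1074 were higher and 1895 lower.

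The interaction asked whether the dorsoventral difference itself differed between spinal cord and forebrain. It is the log2 fold change of VSC over DSC minus that of VFB over DFB. FOSB (6.44 ± 0.73), GSX2 (6.17 ± 0.49), NRN1, a neuritin gene (6.12 ± 0.28), and GPD1 (6.09 ± 0.13, limma adjusted p = 7.8e-16) had the largest positive values. The gene with the symbol YSK4 (-9.57 ± 0.55) and IRX1 (-8.95 ± 0.50) were among the largest negative ones. COL3A1, for example, was 8.60 log2 units higher in VFB than in DFB and 0.31 higher in VSC than in DSC (interaction -8.29). Cell cycle genes had a positive interaction for all 22 (list alone 22, camera adjusted p = 4.65e-13, adjusted p = 0.096 with an estimated correlation). Matrix genes had a negative interaction for 26 of 30 and a positive for 3 (list alone 26 and 3, camera adjusted p = 6.45e-08, adjusted p = 0.096 with an estimated correlation). Interferon response genes were negative for 19 of 23 and positive for 1 (list alone 19 and 1, camera adjusted p = 2.26e-05, 0.0354 with an estimated correlation). Ventral spinal cord genes were negative for 11 of 13 (list alone 13, camera adjusted p = 0.000121, 0.0354 with an estimated correlation).

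**Figure D3:**
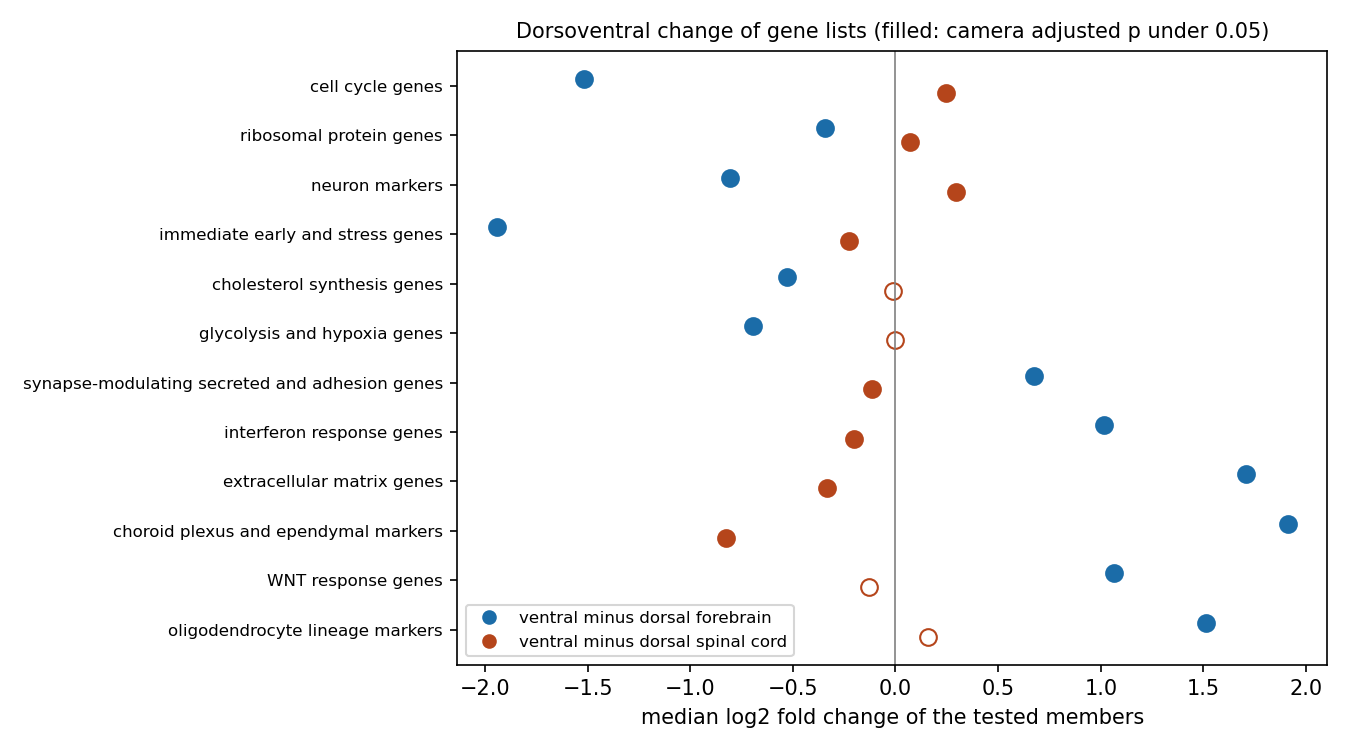
Median log2 fold change of the tested members of 12 gene lists (horizontal axis, 1 list per line) for ventral minus dorsal forebrain (blue) and ventral minus dorsal spinal cord (orange), with members at 0 reads in a group set at their bound and filled points for a camera adjusted p under 0.05. Cell cycle genes had medians of -1.52 and 0.25, and choroid plexus and ependymal markers 1.91 and -0.82.

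Further lists were called in the interaction at the preset correlation. Negative were WNT response genes (11 of 13, list alone 11, camera adjusted p = 0.00139, adjusted p = 0.161 with an estimated correlation). So were synapse-modulating genes (16 of 23 with 5 positive, list alone 16 and 5, camera adjusted p = 0.00922, adjusted p = 0.096 with an estimated correlation) and, by the same test, oligodendrocyte markers (11 of 13 with 1 positive, list alone 11 and 1, camera adjusted p = 0.00387, adjusted p = 0.117 with an estimated correlation). So were mesenchymal and fibroblast markers (14 of 17 with 2 positive, list alone 14 and 2, camera adjusted p = 0.00178, adjusted p = 0.096 with an estimated correlation) and choroid plexus and ependymal markers (10 of 14, list alone 10, camera adjusted p = 0.000127, adjusted p = 0.0525 with an estimated correlation). A1-type genes were negative for 6 of 8 (list alone 6, camera adjusted p = 0.0208, adjusted p = 0.384 with an estimated correlation). Pan-reactive genes were negative for 6 of 11 with 1 positive (list alone 6 and 1, camera adjusted p = 0.0439, adjusted p = 0.303 with an estimated correlation). Endothelial markers were negative for 8 of 10 with 1 positive, with TEK at -5.51 (list alone 8 and 1, camera adjusted p = 0.0229, adjusted p = 0.117 with an estimated correlation). Positive were cholesterol synthesis genes (17 of 21 with 1 negative, list alone 17 and 1, camera adjusted p = 0.000187, adjusted p = 0.243 with an estimated correlation) and glycolysis and hypoxia genes (19 of 24 with 4 negative, list alone 19 and 4, camera adjusted p = 5.44e-05, adjusted p = 0.303 with an estimated correlation). Ribosomal protein genes (28 of 30, list alone 30, camera adjusted p = 1.16e-07, adjusted p = 0.371 with an estimated correlation) were also positive. So were immediate early and stress genes (13 of 19 with 5 negative, list alone 14 and 5, camera adjusted p = 0.00139, adjusted p = 0.417 with an estimated correlation) and neuron markers (13 of 20 with 3 negative, list alone 13 and 3, camera adjusted p = 0.00178, adjusted p = 0.196 with an estimated correlation). The call of pan-reactive astrocyte genes was lost without DFB replicate 2 (0.071), without DFB replicate 3 (0.0724) and with replicate block (0.053), and that of endothelial markers was lost under quantile normalization (0.067). Their adjusted p ranged from 0.02 to 0.0724 and from 0.0159 to 0.067 over the settings.

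The interaction was positive for 4798 genes and negative for 5469, with 1270 and 2613 of them at 2-fold or more, and camera called 17 of 36 lists. Quantile normalization turned the majority, with 5644 positive and 4807 negative. Across 16443 genes, the dorsoventral log2 fold changes of spinal cord and forebrain correlated with r = -0.140 (Spearman's rho -0.168). Of the called genes, 954 were higher in VFB and lower in VSC, against 604 for independent calls, and 574 were lower in VFB and higher in VSC, against 366. Fewer than under independence went the same way, with 389 higher on both ventral sides against 409 and 426 lower against 541. The rostrocaudal fold changes of the dorsal and ventral sides correlated with r = 0.392 (rho 0.291), with 2851 genes higher on both sides against 1861 for independent calls and 2390 lower against 1732. Neither pair of contrasts shares a library.

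Some lists were not called in any comparison. In VFB against DFB, inflammatory cytokines and chemokines had 4 higher, 5 lower and 5 not called of 14, with IL11 at -3.07 and ICAM1 at 1.79 (list alone 4 and 5, camera adjusted p = 0.919). A2-type reactive genes had 4 higher, 5 lower and 4 not called of 13, with CD109 at 4.18 and SPHK1 at -1.55 (list alone 4 and 5, camera adjusted p = 0.877). BMP and JAK-STAT response genes had 8 higher, 4 lower and 3 not called of 15, with BAMBI at 1.66 and JUNB at -2.90 (list alone 8 and 4, camera adjusted p = 0.733). Pluripotency markers had 2 higher, 3 lower and 7 not called of 12, with POU5F1 not called at 52.3 ± 12.7 in DFB and 54.6 ± 1.26 in VFB and DNMT3B at -2.34 (list alone 2 and 3, camera adjusted p = 0.596).

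In several lists without a call, the median, the mean and the camera direction differed in sign. In spinal cord against forebrain these included the dorsal forebrain list (median -0.27 over 13 genes, mean 0.34, direction up). Its median was 0.27 with genes at 0 reads at their bound and 1 gene with few reads left out. Another was the ventral spinal cord list (median -0.56 over 13 genes, mean 0.02, direction down). Its median was 0.34 at the bound, with 5 of the 13 genes left out. The synapse-modulating, A2-type, pluripotency and choroid plexus lists also belonged here. In VFB against DFB they were the hedgehog (median -0.03, mean 0.89, direction up), A2-type, inflammatory and muscle lists. In VSC against DSC they were the ventral forebrain, ventral spinal cord, glutamate handling, neural crest and blood-brain barrier lists. In DSC against DFB they were the A2-type, BMP and JAK-STAT, glycolysis and pluripotency lists. In VSC against VFB they were the matrix (median 0.07, mean -0.40, direction up), mesenchymal, oligodendrocyte, hedgehog, blood-brain barrier and pluripotency lists. In the interaction they were the A2-type, progenitor and pluripotency lists. In the interaction the median changed sign at the bound for the forebrain transcription factors (-2.13 to 0.14). It also did so for the HOX paralogue groups 6 to 9 (-1.52 to 1.73) and the dorsal forebrain list (-0.66 to 0.22). In this order, the medians at the bound left out 4 of 12, 8 of 9 and 6 of 13 genes. The change of sign therefore cannot be put down to the bound alone.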

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

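The tests of explanations in this part were chosen after the results were seen, except the splits for list counts.

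What drew attention to the results of this paragraph and the next was a tested difference between effects, the interaction of side and axis, while the 3 patterns weighed after them are differences between groups. The interaction was called for 10267 genes and 17 lists. Of 100 groupings of the samples, 1 (the real one) reached the gene count, with 3937 the highest other count, and 4 reached the list count, with 18 the highest other. In the main comparison of spinal cord with forebrain, 1 of 100 groupings reached the 11639 genes (highest other 3900) and 6 reached the 15 lists (highest other 17), so chance is not excluded for that number of lists. Groupings that mix libraries of different groups carry the differences between groups as spread. They therefore cannot show that either gene count is particular to its contrast. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of these comparisons 1 split, the real one, reached the gene count and 1 the list count. The real gene counts were 11401, 2769, 11727 and 10073 (VFB against DFB, VSC against DSC, DSC against DFB, VSC against VFB), against a highest other of 1, 0, 0 and 1. The list counts were 14, 15, 21 and 11 against 11, 8, 16 and 10.

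The lists called on both sides with opposite directions had median interactions of -0.57 (synapse-modulating genes), -1.27 (interferon response), -2.07 (matrix), 1.78 (cell cycle), 0.42 (ribosomal proteins), 1.34 (neuron markers) and -2.52 (choroid plexus and ependymal markers). With genes at 0 reads set at their bound, and genes with at most 3 reads in both groups of a side left out, the interferon median was -1.29 and the matrix median -2.07. Single genes had interactions of 5.83 (GABRP), -8.76 (NDNF), -9.33 (PAX3) and -8.63 (SLITRK6) for the dorsoventral effect, and -9.59 (MMRN1) for the axis effect. Each of these genes had a group with few or no reads, so its fitted value depends on the pseudocount and is no bound.

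Immediate early genes were higher in DFB than in the other groups, with a median log2 difference of 3.64. For 8 of 8 such genes all 3 DFB libraries lay above the other 9, which argues against a single library as the source. ERK feedback genes, which ERK signalling induces, had a median difference of 1.99 (quartiles 1.17 to 3.25, 11 of 12 higher, IER3 lower). SPRY4, seen before the list was drawn up, averaged 4941 against 153, 271 and 186, and the median was 1.84 without it. The median of all 12 was above the limit set for handling shortly before lysis as the only source, a limit written after the results were seen. How fast these genes respond was not measured, so neither brief handling nor a stimulus of an hour or more is excluded. The median of 1.99 also reached the limit set for sustained ERK signalling in DFB cells, and no test here separates that from other stimuli.

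HOXB6 to HOXB9, PAX3 and PAX7 were lower in VSC than in DSC, with a median of -5.85. After quantile normalization the median of the 6 genes was -5.71, which argues against scaling. A general shift towards anterior identity stays open, since the 9 tested HOX genes of groups 6 to 9 had a median of -1.52 and went both ways. The genes called lower were all HOXB, 0 of the 5 HOXA and HOXD genes was called, HOXA7 went from 96.6 to 136, and HOXA9 (-1.52) and HOXD9 (1.33) had few reads. Neural crest cells in the DSC libraries stay open too, since that list also went both ways (median -0.0738, 12 genes, quartiles -0.47 to 0.58), as does the dorsoventral difference named in the labels, which was not tested.

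The 7 GABAergic genes GAD1, GAD2, SLC32A1, DLX1, DLX2, DLX5 and DLX6 were higher in DFB than in VFB, with a median of -4.75 for VFB over DFB. All 7 also averaged more in DFB than in either spinal cord group, so the pattern is not limited to the forebrain comparison. GAD1, for example, averaged 5478 in DFB, 713 in VFB, 616 in DSC and 807 in VSC. The fixed ventral forebrain list, with 7 of 16 genes higher in VFB and 9 lower, cannot decide whether labels were exchanged. It holds the DLX genes of this pattern beside NKX2-1 and LHX6, which went the other way. NKX2-1 (987 against 3.43), LHX6 (88.1 against 0.297), LHX8 (30.4 against 0.802), SHH (28.1 against 0) and FOXA1 (174 against 0.891) were higher in VFB, as the labels would have it. No tested gene of the ventral spinal cord list was called lower in VFB, while the dorsal forebrain list went both ways. Mature neurons in the DFB libraries stay open, since pan-neuronal genes went both ways (median -0.78, 13 genes, quartiles -1.35 to 0.25, 8 lower and 3 higher), and genes with a high level in both groups, like MAP2, would hide a small share of neurons. Immature neurons stay open as well, with DCX at -3.03, since bulk values cannot place it in cells other than the glia. The dorsoventral difference named in the labels was not tested apart from these.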

How the results depend on the processing

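The voom test was chosen after the results were seen, the other alternatives before. No called list and no named gene changed direction. Of 822 pairs of a named gene and a comparison, 43 lost their call under at least 1 alternative other than a threshold, 29 of them when 1 library was left out. Pairs whose gene was no longer tested under a setting were not counted as lost there. With the filter at 5, 796 pairs kept their call and 3 lost it. Without VFB replicate 1, 800 kept it and 7 lost it. The remaining pairs of these settings had no result. With a log2 fold change of at least 1, counts were 2965 (spinal cord against forebrain), 3727 (VFB against DFB), 537 (VSC against DSC), 4106 (DSC against DFB), 2969 (VSC against VFB) and 3883 (interaction), and lists 8 (VFB against DFB), 1 (VSC against DSC), 4 (VSC against VFB) and 11 (interaction), as a stricter threshold must lower them. An adjusted p under 0.01 left 1619 genes and 8 lists in VSC against DSC. With an estimated correlation, camera called 3, 0, 0, 1, 3 and 2 lists in the same order of comparisons, against 15, 14, 15, 21, 11 and 17 of 36. With fry it was 35, 31, 25, 34, 29 and 34, since fry does not compare a list with other genes. The axis correlation of 0.392 was 0.345 and 0.415 with pseudocounts of 0.1 and 5, 0.402 with the filter at 5 and 0.415 after quantile normalization, where the dorsoventral correlation was -0.114 and the median interaction over all genes went from -0.05 to 0.08. The cause was not tested. Quantile normalization also moved the share of called genes that were higher in VSC than in DSC from 40.4% to 49.4% and turned the majority direction in VFB against DFB, DSC against DFB and the interaction, as printed with those counts. With replicate number as a block, counts were 11616, 11360, 2666, 11689, 10046 and 10216, and residuals of libraries with the same number correlated at -0.0664 to 0.0635 across genes. Depth limits genes near 0 reads, where only bounds or wide counting intervals could be given.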

Other observations

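No tests were chosen for this part after the results were seen, and its values carry no explanation.

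SEMA3C, which encodes a secreted guidance cue, averaged 19.8 ± 2.02 in DFB, 346 ± 15.96 in VFB, 2065 ± 65.4 in DSC and 3785 ± 119 in VSC. GPR17, a receptor gene of early oligodendrocytes, averaged 187 ± 27.5 in VFB against 1.40 ± 0.375 in DFB. NEFL, a neurofilament gene, averaged 262 ± 89.8 in DFB and 3747 ± 194 in VFB, unlike most neuron genes, which were higher in DFB.

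The authors deposited posterior probabilities for 5 patterns that the file does not define. Above 0.95 there were 4802, 6252, 3180, 404 and 484 genes in patterns 1 to 5, and some genes had no probability. The group whose mean lay farthest from the others was DFB for 37.9%, VFB for 27.2%, DSC for 16.8% and VSC for 18.03% of the genes of pattern 1. It was DFB for 98.1% of the genes of pattern 2, VFB for 92.8% of pattern 3, DSC for 79.95% of pattern 4 and VSC for 90.3% of pattern 5.

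A deposited sheet gives group means for 53 genes, and all 4 means were equal to those of the main sheet for all 53, within a relative tolerance of 1e-06. Of these genes 48 were tested, with 15 higher and 14 lower in VFB than in DFB, 19 higher and 14 lower in DSC than in DFB, and 5 higher and 6 lower in VSC than in DSC. The mean was highest in DFB for 15 of the 48 tested genes.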
